A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 18 samples.

How the data were processed

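RNA from 18 libraries of Synechococcus elongatus PCC7942 was compared in 4 groups, WT (n = 6), OX-D53E with IPTG (n = 6), OX-D53E without IPTG (n = 3) and OX-Empty with IPTG (n = 3), as the labels name them. Per the labels' protocols, rRNA was depleted, libraries were prepared with a kit that keeps strand, and cultures were held at a near constant optical density by dilution. Per the submitters' processing notes, Bowtie 0.12.9 was used. The genome build and the counting tool are not given in the sources used here.

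The authors deposited a single table with 1 signal value per gene and library, a linear read density. The unit was worked out from the values: within a gene the values over the 18 libraries are whole multiples of a step, and each step is a library factor divided by a whole-number length. Under this reading a value is RPKM divided by 1000. Whole reads were recovered for 2708 of the 2709 rows with a value above 0, with every value above 0 within 0.1 read of a whole number, and 100% of the 2610 numbered loci with a recovered length had a length that is a multiple of 3 (coding length). Recovered reads per library ran from 512632 to 1102066, which sets the counting precision, and the row Synpcc7942_R0017 was the 1 not recovered. No pair of libraries agreed within sampling noise, as the lowest chi-square per gene of reads was 1.95, so none was treated as the same sample.

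The table gives locus IDs and no gene names. The reference table (assembly ASM3054490v1) matched 0 of the IDs, so loci are printed by ID, at most 2 per direction and comparison. The exceptions are 10 clock genes whose locus numbers were listed in advance: kaiA, kaiB, kaiC, rpaA, rpaB, sasA, cikA, labA, ldpA and pex. The recovered lengths of rpaA (750 bp), kaiC (1560 bp) and kaiB (309 bp) equal those in the reference table, although 5, 1 and 8 other rows share these lengths. Lists by product or symbol, such as sigma factors, ribosomal proteins and photosystems, were planned and could not be matched, so no result is given for them, and the planned condition on product names was not applied. Loci were named by the planned order of size among those past the threshold, and on induction among those whose 4 induced libraries all lay outside the range of the uninduced ones. Of 2723 rows, 8 carry a plain number in place of an ID and were kept out of the tests, with a share of at most 0.0385% of reads per library, and 14 were at 0 in all 18 libraries.

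Tests used limma 3.58.1 in R 4.3.3 (eBayes with a trend) on log2(density + 0.00863), where the pseudocount is the percentile 5 of all positive values and corresponds to between 6.10 and 13.0 reads of a 1000 bp locus. Fold changes are on that scale and understate the change of low genes. Genes above the pseudocount in at least 4 libraries of a fit were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. The WT rhythm was a 24 h cosine with a moderated F test; dusk genes had a fitted peak within 6 h of ZT 36 and dawn genes the rest. Induction was fitted with terms for strain and for the 0.5 h library. With these terms it is the difference between 4 libraries (OX-D53E with IPTG at 2, 3, 6 and 12 h) and the 4 uninduced OX-D53E libraries. The OX-Empty libraries, which with these make up the 7 uninduced OX libraries, add only to the estimate of spread. IPTG alone and time alone were terms of a factorial model of the 12 OX libraries. Gene sets were tested with camera (preset correlation 0.01, and an estimated one) and fry. Because the unit holds no deposited counts, no count test was the main test, and voom on the recovered reads was run as an alternative chosen after the data were seen.

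The code was tested on simulated reads with the real means and library factors, with 200 genes changed. At 2-fold, 97.0% of changed genes were recovered for induction, 65.7% for the WT rhythm, 100% for the deletion strains, 50.7% for IPTG alone and 91.0% for time alone. The simulated dispersion was held at a floor of 0.005, taken from 6 uninduced libraries without the deviating 0 h library, and only well-covered genes were changed, so these shares are upper limits and check the code more than the power of the real tests. Of the simulated calls, 2.78% for induction and 6.45% for the WT rhythm fell on unchanged genes. Alternatives covered the pseudocount, the filter on low values, scaling, the variance model, the threshold, the period, the controls, and leaving out each library.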

Results

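Transcript levels were measured by strand-specific RNA sequencing of rRNA-depleted RNA in 18 libraries of the cyanobacterium Synechococcus elongatus PCC7942. The wild-type (WT) culture was sampled 6 times over a circadian cycle in constant light, from ZT 24 to ZT 44, where ZT is the time in hours after release into constant light. The other 12 libraries came from strains that lack the response regulator gene rpaA and the clock genes kaiB and kaiC. Strain OX-D53E carries RpaA D53E, a form that mimics phosphorylated RpaA, behind an IPTG-inducible promoter, and strain OX-Empty carries the same promoter with no gene behind it. OX-D53E with IPTG was sampled at 0, 0.5, 2, 3, 6 and 12 h, OX-D53E without IPTG at 0, 3 and 12 h, and OX-Empty with IPTG at 0, 3 and 12 h. The 0 h samples were taken before 100 µM IPTG was added. Each time point was a single library from a single culture, so no p-value below can be read as measuring the spread between independent cultures. The limma p-values rest on the spread of libraries around each fit, which for the WT rhythm is the departure from a cosine. Fisher's test, camera and the shuffles of locus order compare genes. The rows of the deposited table held between 512632 and 1102066 recovered reads per library, with a median of 59 reads per numbered locus and library.

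The targeted genes followed the library labels. The rpaA transcript was at a read density (RPKM divided by 1000) of 0.426 in OX-D53E before IPTG and at 34.6 after 0.5 h, a 75.9-fold rise over the mean of the 2 OX-D53E libraries at 0 h. It stood at 46.0 at 2 h, when it took 4.68% of the recovered reads, and at 17.8 at 12 h. Without IPTG, rpaA in OX-D53E lay between 0.302 and 0.487 at 0, 3 and 12 h. The 6 WT libraries lay between 0.344 and 0.614, so the uninduced strain carried about as much rpaA mRNA as WT. In OX-Empty, rpaA was between 0.00447 and 0.00642, which corresponds to 12 reads over 3 libraries. The kaiB transcript, which encodes a protein of the KaiABC oscillator, had 2 reads in the 12 OX libraries together and 811 in the 6 WT libraries (ratio 0.00181, exact 95% interval for counting error only 0.000219 to 0.00657). The kaiC transcript, which encodes the central clock ATPase, had a mean density of 0.0208 ± 0.00824 (SD, n = 12) in the OX libraries and 0.286 ± 0.189 (SD, n = 6) in WT. Unlike kaiB, the deleted kaiC locus kept 17 to 51 reads in every OX library (342 in all). The source of these reads was not tested.

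**Figure D1:**
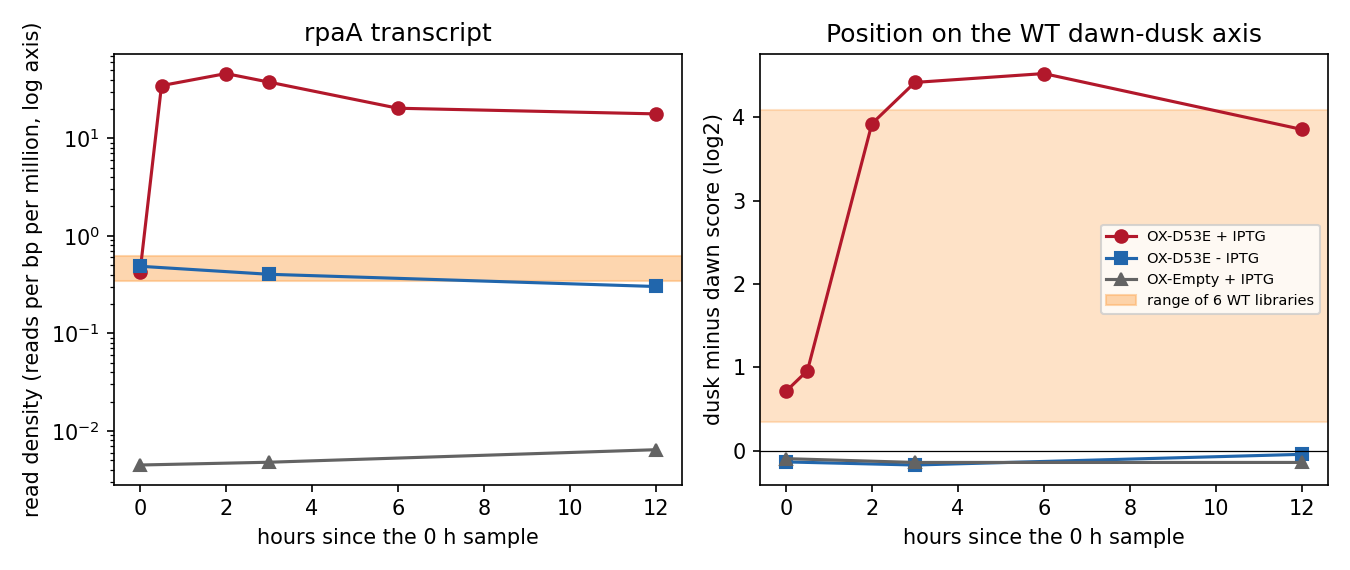
Left, rpaA read density on a log axis against hours since the 0 h sample in the 3 OX cultures, 1 point per library, with the range of the 6 WT libraries shaded. Right, the dusk minus dawn score (log2) of the same libraries, with the range of the 6 WT libraries shaded; in the culture that received IPTG, rpaA reached 34.6 by 0.5 h while the score was 0.96, and the score stood at 3.92 by 2 h.

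The WT time course asked which transcripts cycle in constant light. Most of the transcripts called rhythmic peaked at subjective dusk. Of 2547 genes tested, 128 peaked within 6 h of ZT 36 (dusk genes) and 16 peaked outside that window (dawn genes) at an adjusted p under 0.05 in limma's moderated F test of a 24 h cosine. The fitted peak-to-trough amplitude had a median of 2.10 on the log2 scale in dusk genes and 1.77 in dawn genes. The fitted peak lay between ZT 34 and ZT 38 in 126 of the dusk genes, and 114 had their highest value at ZT 36. The fitted peak of 15 of the 16 dawn genes lay between ZT 24 and ZT 28. Among the genes of the clock, kaiB (amplitude 2.00, limma adjusted p = 0.00756), kaiC (2.65, adjusted p = 0.00282) and cikA (1.67, adjusted p = 0.0396), which encodes a histidine kinase that passes timing information to RpaA, were called as dusk genes. The cikA transcript was not called with quantile normalization (adjusted p = 0.0796) or a 26 h period (adjusted p = 0.0786), or without the library at ZT 28, 32, 36 or 40 (adjusted p between 0.0762 and 0.222). The kaiC density was 0.0950 at ZT 24 and 0.557 at ZT 36. The dusk genes of largest amplitude were locus Synpcc7942_1849 (amplitude 6.21), with 20 reads at ZT 28 and 3631 at ZT 36, and locus Synpcc7942_B2638 (5.18), with no read at ZT 28 and 191 at ZT 36. Among dawn genes these were Synpcc7942_0905 (amplitude 3.11), at 11.8 at ZT 28 and 1.47 at ZT 40, and Synpcc7942_0855 (2.63), at 0.676 at ZT 24 and 0.123 at ZT 40. With 1 cycle and 3 residual degrees of freedom, the calls rested on moderation across genes. An ordinary F test called 0 genes after adjustment, where limma's moderated F test called 144. At an unadjusted p under 0.05 limma had 421 genes. Without the ZT 36 library 63 dusk genes were called, and without the ZT 44 library 41 dawn genes. Synpcc7942_1849 (adjusted p = 0.0639) and Synpcc7942_B2638 (adjusted p = 0.053) were not called without ZT 36, nor Synpcc7942_0905 (adjusted p = 0.0593) without ZT 28.

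Induction of RpaA D53E asked which transcripts respond to the phosphomimetic regulator in cells without a clock. Over 2, 3, 6 and 12 h of IPTG, 392 genes rose and 342 fell, of 2627 tested (limma, adjusted p under 0.05). Because of the term for strain, the change is against the 4 uninduced OX-D53E libraries, and the OX-Empty libraries add only to the estimate of spread. The median change was 1.14 on the log2 scale in the rising genes and -0.74 in the falling genes, and a change of at least 1 log2 was seen in 228 rising and 93 falling genes. Over all genes tested, the 4 induced libraries lay above all 7 uninduced libraries in 328 genes (12.5%) and below them in 281 (10.7%), where exchangeable libraries give 0.303% in each direction. Apart from rpaA itself (log2 change 6.11 ± 0.28, SE), the largest rises among genes whose 4 induced libraries lay apart from the 7 uninduced ones, on the log2 scale with the pseudocount, were in Synpcc7942_2336 (6.21 ± 0.37, limma adjusted p = 1.12e-07) and Synpcc7942_1611 (6.13 ± 0.34, adjusted p = 6.75e-08). The density of Synpcc7942_2336 was 0.0335 ± 0.0183 (SD, n = 7) in the uninduced libraries and 2.54 ± 0.713 (SD, n = 4) in the induced ones, above its highest WT value of 1.05. Synpcc7942_1611 had 9 reads over the 7 uninduced libraries and 930 over the 4 induced ones. Of the genes that fell, Synpcc7942_R0030 had 40 reads over the uninduced and 2 over the induced libraries (ratio 0.0868, exact 95% interval for counting error only 0.0102 to 0.335; limma adjusted p = 0.000186). This row is 73 bp long, with at most 1 read per induced library and at least 2 per uninduced one. It is 1 of 24 R-numbered rows that fell, of 40 tested. These rows moved together (camera p = 0.161 with an estimated correlation of 0.479), so its fall may not be its own. Synpcc7942_0905 was at 15.3 ± 8.85 (SD, n = 4) in the uninduced OX-D53E and 1.90 ± 1.06 (SD, n = 4) in the induced libraries (log2 change -2.84 ± 0.57, SE, adjusted p = 0.00266). However, it stood at 3.25 in the OX-D53E culture that was to receive IPTG, before IPTG was added. That culture's 0 h library differed from the other 6 uninduced libraries, and with a term for the culture, which sets the induced libraries against their own 0 h library, 254 genes rose and 181 fell and Synpcc7942_0905 was no longer called (-0.94, adjusted p = 0.277). The counts also depended on the model and the libraries in it, at 94 rising and 7 falling genes in a factorial model with IPTG and time terms and 121 and 55 with the 0, 3 and 12 h libraries alone and terms for arm and time, and quantile normalization moved the share of rising genes among the calls from 53.4% to 40.7%.

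The dusk genes rose later than the rpaA transcript. At 0.5 h rpaA was already at 34.6, and it was the 1 gene past the threshold in limma. That test rests on 1 library and cannot show that other genes did not respond. Against the mean of the 2 OX-D53E libraries at 0 h, the median log2 difference of the WT dusk genes was 0.08 at 0.5 h, 2.01 at 2 h, 2.49 at 3 h, 2.54 at 6 h and 2.21 at 12 h. The medians of the WT dawn genes were -0.57, -1.58, -1.54, -1.49 and -1.16 at the same times. Against the 0 h library of the same culture they were 0.05, -0.89, -0.98, -1.15 and -0.74, and the dusk medians were 0.21, 2.22, 2.65, 2.64 and 2.39. Against the OX-D53E library without IPTG at the same time, dusk genes stood at 2.27 at 3 h and 2.21 at 12 h, and net of the change in OX-Empty they stood at 2.43 and 2.11. A score per library, the mean log2 level of the dusk genes minus that of the dawn genes centred on the uninduced libraries, was 3.92 at 2 h, 4.42 at 3 h, 4.52 at 6 h and 3.85 at 12 h after IPTG. The 6 control libraries lay between -0.17 and -0.04, and the culture that was to receive IPTG stood at 0.71 at 0 h and 0.96 at 0.5 h. The 4 induced libraries exceeded the 7 uninduced ones by 4.18 (exact permutation test over 330 splits, two-sided p = 0.00303, the smallest it can give), and by 2.63 with the 200 dusk and 200 dawn genes of largest amplitude. WT reached 4.09 at ZT 36 and 0.34 at ZT 28 on this scale, which is circular for WT because the gene sets were chosen on those libraries. The dawn genes of the IPTG culture were already low before induction, at a mean of -0.91 at 0 h against 0.02 to 0.29 in the other 6 uninduced libraries.

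Genes with a WT rhythm moved on induction toward their dusk level. Of the 127 dusk genes tested in both, 118 rose and 0 fell, and of the 16 dawn genes 15 fell and 0 rose (Fisher's exact test on the called genes, two-sided p = 4.12e-20). The median induction change was 2.24 on the log2 scale in dusk genes, -1.62 in dawn genes and -0.06 in genes with no rhythm called. With a term for the IPTG culture it was 2.50 in dusk genes and -0.92 in dawn genes. Of the 2401 genes with no rhythm called, 260 rose and 327 fell. Across 2544 genes, which are not independent replicates, the induction change and the WT dusk minus dawn contrast had a Pearson r of 0.79 and a Spearman rho of 0.61, and the 2 estimates share no library. As a set, dusk genes rose relative to other genes (camera adjusted p = 4.85e-68, and adjusted p = 0.000528 with an estimated correlation) and dawn genes fell (adjusted p = 7.96e-10, and adjusted p = 0.02 with an estimated correlation). The call for dawn genes was less firm, as 56.25% of them fell with a term for the IPTG culture and 6.25% in the factorial model, while 85.04% and 56.69% of the dusk genes still rose. Among the 200 dawn-phase genes of largest amplitude, called in WT or not, 80 fell and 4 rose. Of the 198 such dusk-phase genes tested, 164 rose and 1 fell.

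**Figure D2:**
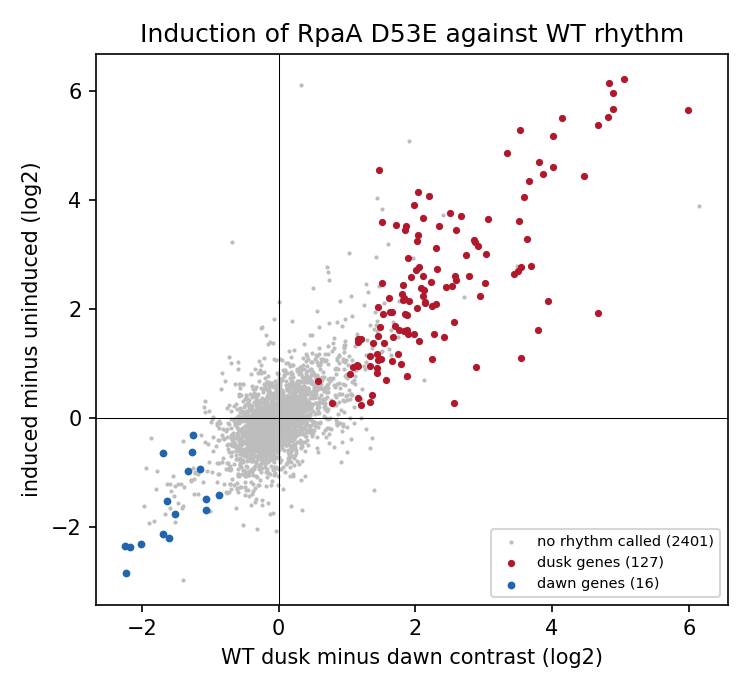
Each point is a gene, coloured by WT class, with its WT dusk minus dawn contrast (log2) on the x axis. The y axis is its change on induction (4 induced minus 4 uninduced OX-D53E libraries, log2). The 127 dusk genes lie above 0 with a median of 2.24, the 16 dawn genes below 0 with a median of -1.62, and Pearson's r across 2544 genes is 0.79.

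IPTG by itself and time by itself were tested with OX-Empty and with OX-D53E without IPTG. Both terms also used the OX-D53E libraries at 0 h as a baseline. The 0 h library from the culture that was to receive IPTG deviated from the other uninduced libraries. Neither IPTG nor time changed a gene past the threshold. The IPTG term gave 0 of 2627 genes in limma, with 41 at an unadjusted p under 0.05 where 131.4 are expected by chance, and 0 genes with voom on the recovered reads. The time term gave 0 genes in limma, with 57 at an unadjusted p under 0.05 against the same 131.4, and 0 genes with voom. Counts this far below chance can mean that the test was conservative. They are no evidence that IPTG or time had no effect. The smallest p-values for IPTG belonged to Synpcc7942_R0045 (log2 change 2.54 ± 0.68, SE, limma adjusted p = 0.999) and Synpcc7942_1728 (-1.89 ± 0.56, adjusted p = 0.999). For time they belonged to Synpcc7942_1728 (1.36 ± 0.36, adjusted p = 0.995) and Synpcc7942_1685 (-0.85 ± 0.22, adjusted p = 0.995). The baseline of both values includes the deviating 0 h library. Synpcc7942_1728 had 0 reads there and 3 to 13 in the other 6 uninduced libraries. The 3 reads were in the other OX-D53E library at 0 h, so both baseline libraries were low. The density of Synpcc7942_1685 was 0.167 in the deviating library and 0.154 in the other OX-D53E library at 0 h. Its fall thus did not rest on the deviating library alone. The median standard error of the IPTG term was 0.473 on the log2 scale and that of the time term 0.299. With errors of this size, effects of either well above 2-fold could have been missed. The IPTG value of 2.54 that did not pass was in a row with 1 to 7 reads per OX library. It says little about genes with more reads. Without the OX-D53E library at 0 h without IPTG, the deviating 0 h library was the only OX-D53E library at 0 h. Genes then passed for both terms, and an effect of IPTG or time cannot be told apart there from the state of that culture.

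The deletion strains without induction, set against WT, describe the state from which induction started. They held dusk genes below the mean of the WT cycle: 78 of the 128 WT dusk genes were lower in the 7 uninduced OX libraries than in the 6 WT libraries and 0 were higher, and 5 of the 16 dawn genes were higher and 0 lower. The 78 include kaiB and kaiC, which are deleted in these strains. Centred on the uninduced libraries, the dusk gene mean of WT was 0.39 at ZT 24 and 0.42 at ZT 28, against 2.58 at ZT 36. The uninduced strains thus lay near the WT level at ZT 24 and 28 and far below that at ZT 36. The spread of WT in this test includes its rhythm. In all, 78 genes were higher and 151 lower, of 2610 tested (limma, adjusted p under 0.05). Besides the deleted kaiB and kaiC, the lowest were Synpcc7942_B2621 (log2 difference -4.72 ± 0.33, SE, adjusted p = 5.93e-07) and Synpcc7942_0013 (-4.50 ± 0.33, adjusted p = 6.79e-07). Synpcc7942_B2621 was at 0.0167 ± 0.00763 (SD, n = 7) in the uninduced OX libraries, 0.166 ± 0.114 (SD, n = 4) in the induced ones and 0.735 ± 0.437 (SD, n = 6) in WT. The higher genes included Synpcc7942_0905 (2.08 ± 0.54, adjusted p = 0.0293) and Synpcc7942_0084 (1.86 ± 0.17, adjusted p = 1.28e-05), the latter at 0.135 ± 0.0141 (SD, n = 7) against 0.0324 ± 0.0123 (SD, n = 6) in WT. The strains differ from WT in resistance markers and culture run as well as in rpaA and kaiBC, and these cannot be told apart. The group is mixed for rpaA mRNA, with a mean density of 0.405 in 4 uninduced OX-D53E libraries, 0.00522 in 3 OX-Empty libraries and 0.487 in WT. The mean log2 level of the dusk genes, centred on the uninduced libraries, was -0.20 to 0.05 in those OX-D53E libraries and 0.01 to 0.15 in OX-Empty. The -0.20 was in the deviating 0 h library. Among the uninduced OX libraries alone, the dusk gene mean was thus no lower in OX-Empty, where rpaA mRNA was lowest. RpaA protein was not measured here. The call for Synpcc7942_0905 was lost without any 1 of 10 of the 13 libraries, those at ZT 32 to 44, OX-D53E without IPTG and OX-Empty (adjusted p between 0.0509 and 0.0784). Without the ZT 32 library 44 genes were higher and 56 lower, and quantile normalization moved the share of higher genes among the calls from 34.1% to 44.6%.

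Of the 9 members of the clock and output list that could be tested on induction, 3 rose and 0 fell over all genes tested, and adjusted over the list alone 5 rose and 1 fell. The transcript of cikA rose by a log2 change of 1.94 ± 0.19 (SE, limma adjusted p = 8.77e-06), from 0.0542 ± 0.0039 (SD, n = 4) in the uninduced OX-D53E libraries to 0.239 ± 0.0677 (SD, n = 4). The transcript of kaiA, the activator of KaiC autophosphorylation, rose by 0.76 ± 0.18 (adjusted p = 0.00862), but was at 0.24 with adjusted p = 0.486 with a term for the IPTG culture. The third was rpaA itself. The values of pex (0.42 ± 0.15, adjusted p = 0.0526), sasA (0.30 ± 0.12, adjusted p = 0.0855), labA (-0.36 ± 0.15, adjusted p = 0.0893) and rpaB (-0.26 ± 0.14, adjusted p = 0.173) did not pass. Neither did ldpA (-0.16, adjusted p = 0.41) or kaiC (0.27, adjusted p = 0.442), which is deleted in these strains but counted in the list and its set test. With quantile normalization, which lowers the median of all genes, rpaB (adjusted p = 0.0486) and labA (adjusted p = 0.0483) passed. The call for pex was gained without the lowest quartile of genes (adjusted p = 0.0482), with robust moderation (adjusted p = 0.0464) or without the 6 h library (adjusted p = 0.019). As a set the list was higher on induction (camera adjusted p = 0.0376, and adjusted p = 0.0626 with an estimated correlation), where rpaA is the induced gene and not independent evidence. In the WT dusk minus dawn contrast 4 of 10 members were higher and 0 lower (camera adjusted p = 0.00624, and adjusted p = 0.0647 with an estimated correlation). This count tests the contrast alone and not the rhythm. It adds pex (1.00 ± 0.22, SE) to kaiB, kaiC and cikA. The rhythm of pex was not called (limma moderated F test, adjusted p = 0.0799).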

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

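The tests of the 0 h library, of the share of genes in the WT direction and of the dusk excess in this part were chosen after the result was seen, while the other splits of the samples and the test of genes against the WT direction were set out before their results were seen. Of 74 groups of values examined for a library apart, 6 held such a library, where the nominal chance rate of the rule is 1 in 20 groups. That rate was not estimated from these data.

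The OX-D53E library taken at 0 h from the culture that was to receive IPTG stood at 0.71 on the dusk minus dawn score, apart from the other 6 uninduced libraries. Its standard deviation from those libraries across genes was 0.670 on the log2 scale, against 0.269 to 0.331 for each of them, and 47 genes differed by at least 4-fold, against 1 to 3 in the others. Counting noise is argued against by the chi-square per gene of reads against the OX-D53E library without IPTG at 0 h, 45.7, where pairs of the other 6 libraries reached 5.32. RNA of induced cells is argued against by rpaA, at 0.873 times its highest value in OX-D53E without IPTG, and by a dusk gene mean of -0.20, and a label mix-up with OX-Empty or WT is argued against by rpaA at 66.3 times its highest OX-Empty value and by kaiC below every WT library. The deviations recurred at 0.5 h (r = 0.70 across genes, against -0.11 to 0.12 with the other uninduced libraries) and less so at 2, 3, 6 and 12 h (r = 0.136, 0.213, 0.282 and 0.20), so a state of that culture before IPTG may be the source; what set it is open, and it goes together with the induced libraries of the same culture.

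Of 734 genes called on induction, 587 were also tested in WT and had no rhythm called there. Low power of the WT test may account for most of them: 89.1% had a WT contrast in the direction of their induction change, against 64.4% of genes called in neither, and the simulated recovery of a 1.5-fold rhythm was 10.4% even at a low dispersion. For the 64 genes that went against the WT direction, a state of the culture before IPTG cannot be told apart from an effect of RpaA D53E, since 54.7% (exact 95% interval 41.7% to 67.2%) deviated at 0 h in the direction of their later change, against 43.6% of the 523 genes with the WT direction, and the 0 h library also entered their baseline. The bounds for this test, over 75% for the culture state and at most 60% against it, were set before the result; judging it by the interval in place of the value, which by itself argued against the culture state, was decided after the result was seen. With a term for the IPTG culture, 18 of these 64 genes and 209 of the 523 others stayed past the threshold in the same direction.

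Dusk genes outnumbered dawn genes in WT by 128 to 16. The authors' scaling as the cause is argued against by ratios of at least 6.60 under median-of-ratios and quantile scaling. Low power for small rhythms cannot be told apart from a biological excess of dusk transcripts. Among genes with a fitted amplitude of at least 1 log2, called or not, 228 had a dusk and 73 a dawn phase (75.75% dusk), but this set leaves out the small rhythms in question. Of the 587 genes called on induction alone, 302 fell with a WT contrast below 0 and 221 rose with one above 0.

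A chance assignment of exchangeable libraries is argued against as the source of the 3 large counts. The argument is weaker for the WT rhythm, where only 60 orders were compared. The 100 splits were drawn from 330 possible ones for induction and from 1716 for the deletion strains. The libraries of a culture are repeat samples, so a chance difference between single cultures is not excluded. The real grouping was the 1 of 100 splits of the 11 libraries that gave as many as 733 genes for induction, fitted without the 0.5 h library, where the highest other split gave 31. It was the 1 of 60 orders of the WT time points that gave as many as 144 genes, where the order that exchanged ZT 32 and ZT 40 gave 126. It was also the 1 of 100 splits for the 229 genes of the deletion strains against WT, where the highest other split gave 1.

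The other libraries that stood apart were single high values. The kaiB density in uninduced OX libraries was 0.00855 in OX-D53E without IPTG at 3 h (2 reads) and 0 in the other 6. Synpcc7942_1849 stood at 0.0161 in OX-Empty at 12 h among the uninduced libraries. At 12 h of induction, Synpcc7942_B2621 stood at 0.335 and Synpcc7942_0013 at 0.315, above the other 3 induced libraries, and Synpcc7942_1728 stood at 0.0407 at 2 h. Among the plain-number rows that no comparison used, row 7 had a mean density of 0.0249 ± 0.00556 (SD, n = 4) in induced libraries and 0.00558 ± 0.00139 (SD, n = 7) in uninduced ones, and row 8 had 0.101 ± 0.0257 and 0.0111 ± 0.00438 (exact permutation p = 0.00303 for each, adjusted p = 0.0106 over the 7 rows with reads).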

How the results depend on the processing

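The alternatives were set out before the data were examined, apart from voom on the recovered reads, the term for the IPTG culture, the left-out gene groups and the left-out libraries for the score and the comparison with WT. Smaller and larger pseudocounts, filters, median-of-ratios scaling, the variance model and the period kept every main count within 1.5 times, and no call of a named gene or set changed direction. Quantile normalization also kept the counts within 1.5 times, but turned the balance of the induction calls to 325 rising and 473 falling and moved the median induction change of all genes from -0.03 to -0.14. An adjusted p of 0.01 left 59 dusk and 8 dawn genes, 258 rising and 147 falling genes, and 26 higher and 30 lower genes in the deletion strains; an ordinary F test left 0 dusk and 0 dawn genes. With voom on the recovered reads 25 dawn genes were called and 78 genes were lower in the deletion strains. Induction gave 163 rising and 69 falling genes with 0.5 h counted as induced, 94 and 7 in the factorial model, 121 and 55 with libraries at 0, 3 and 12 h alone, 228 and 93 with a change of at least 1 log2, and 254 and 181 with a term for the IPTG culture. Of the genes that fell in the main test, 21 were among the 55 and 115 among the 181; of those that rose, 113 were among the 121 and 238 among the 254. Dusk genes that rose made up 82.83% and dawn genes that fell 40.0% with the 200 genes of largest amplitude in each class, 56.69% and 6.25% in the factorial model, and 85.04% and 56.25% with the culture term. With an estimated correlation the clock list had adjusted p = 0.0626 on induction and 0.0647 in WT. Leaving out each library gave 63 (without ZT 36) to 116 dusk genes, 9 (without ZT 28) to 41 (without ZT 44) dawn genes, 334 to 400 rising and 234 to 354 falling genes, 44 (without ZT 32) to 102 higher and 56 to 209 lower genes in the deletion strains, and 0 to 8 genes for IPTG and 0 to 18 for time, the highest without the OX-D53E library at 0 h without IPTG. Without that library, the deviating 0 h library of the IPTG culture was the only OX-D53E library at 0 h. Leaving out OX-Empty at 0 h made the factorial model impossible to fit, so it has no value. The induced minus uninduced score stayed between 4.06 and 5.10, and was 2.63 with the 200 genes of largest amplitude in each class. The share of dawn genes that fell ran from 81.25% (without any 1 of 5 OX-D53E libraries) to 100% (without ZT 28 or ZT 36) when each library was left out. The causes were not tested. Depth limits genes near the pseudocount.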

Other observations

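The tests of neighbouring loci and of the R-numbered and B-numbered rows were chosen after the data were seen. Induced changes came in runs of consecutive loci. Of 2504 pairs of loci with consecutive numbers, 245 were called in the same direction on induction, against a mean of 94.7 and a highest of 126 in 10000 shuffles of the locus order (permutation test, one-sided p = 0.0001, the smallest they can give), and 50 were called in opposite directions, against a mean of 93.1. There were 12 runs of at least 4 consecutive loci that rose and 5 that fell; the longest held 14 loci with a median log2 change of -1.18, and a run of 7 rose by a median of 3.59. Shared transcripts of neighbouring loci are a candidate explanation for the 245 pairs, since consecutive loci often form operons, but the files give no coordinates or strand and this was not tested further.

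Among the 53 rows with an R number, 40 are 71 to 89 bp long. Of the 40 R-numbered rows that were tested on induction, 24 fell and 0 rose, with a median log2 change of -1.21 (camera p = 8.26e-09, and p = 0.161 with an estimated correlation of 0.479). In the WT dusk minus dawn contrast their median was -1.40 with 0 of 40 past the threshold. Without these rows, 389 genes rose and 315 fell on induction. Of 34 B-numbered rows tested on induction, 9 rose and 2 fell (camera p = 0.0187, and p = 0.0267 with an estimated correlation). In the WT dusk minus dawn contrast 3 of 29 were higher and 0 lower (camera p = 0.0325, and p = 0.123 with an estimated correlation).

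A run of 6 consecutive loci, chosen after their values were seen, had a mean density of 0.0181 in the OX-D53E culture before IPTG, against 0.567 to 0.741 in the other 6 uninduced libraries and 0.517 to 0.635 in WT. In the same culture the mean was 0.0433 at 0.5 h, 0.0182 at 2 h, 0.0307 at 3 h, 0.197 at 6 h and 0.232 at 12 h. None of the 6 was called on induction by limma, with adjusted p between 0.182 and 0.306 and 0 of 6 at an unadjusted p under 0.05.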
